A study of Homo sapiens with 6 samples.

How the data were processed

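RNA of TC28a2 cells, an immortalised human chondrocyte line, was taken 48 hours after transfection with a control vector (3 samples) or an FAP overexpression vector (3 samples) and sequenced as DRUG-seq libraries, per the labels. The deposited table holds whole-number read counts per gene for the 6 samples, not normalized. The submitters' processing notes name HISAT2, an aligner, featureCounts and Subread, which assign reads to genes, and the GRCh38 build. Versions, strand setting, treatment of reads with several alignments and use of molecular identifiers are not given in the sources used here. Counting without strand can move reads between overlapping genes, counting of multiple alignments can place a read at several copies of a gene, and without molecular identifiers amplification copies count as separate reads. DRUG-seq as generally described primes at poly(A) tails, which would measure non-polyadenylated transcripts, such as most histone RNAs, poorly.

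The table has 28395 Entrez gene IDs, of which 27745 matched a symbol and a GRCh38.p14 position in NCBI's RefSeq gene table; coordinates are given in that assembly. Each column carried the group and replicate of 1 sample. Groups came from the labels. Total counts ran from 5736056 to 13839743 per library. Replicates of a group differed by more than sampling noise, with chi-square per degree of freedom of 5.47 to 7.08 between controls, 5.99 between FAP replicates 1 and 2, and 17.2 and 16.9 between these and FAP replicate 3, so none was treated as a duplicate.

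Counts were analysed with edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr by group (minimum count 10, minimum total 15) and the two-sided quasi-likelihood F test (glmQLFit, glmQLFTest) of FAP minus control, with no covariate. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 13373 genes that passed the filter. The standard error of a log2 fold change is its size divided by the square root of F. The common biological coefficient of variation was 11.8%. Gene lists were tested with camera of limma 3.58.1 (preset correlation 0.01, adjusted over the 26 lists with at least 5 tested members), with an estimated correlation and with fry. Group comparisons of library totals used an exact permutation test.

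The design, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule names FAP, then, among called genes with a mean of at least 10 CPM, a symbol that is not a LOC, antisense or clone name, and all 3 FAP libraries on the same side of all 3 controls, the 10 with the largest log2 fold change in each direction. If fewer pass, all are named, and if fewer than 5 pass in total the 10 with the smallest p are also named as not passing. For each list it adds the 3 called members with the smallest p or, in a described list with none, the 2 members with the smallest p as values, and always ZEB1, ZEB2, CDKN1A, CDKN2A, SOX9, ACAN, COL2A1, COL1A1, FN1, MMP1, MMP3, MMP13, ADAMTS5, IL6, CXCL8 and DPP4. Members past the threshold adjusted over a list alone and called genes outside the rule were named after their values were seen. Results of some genes that the rule or the lists take in are not reported here by name; counts and list tests include them.

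Alternatives were DESeq2 1.42.0, limma-voom, other size factors, FAP or ribosomal protein genes left out, other filters and thresholds, counts thinned to the smallest library, the replicate number as a block, and each library left out in turn. A per-library correction for transcript length and GC content (smooths fitted with mgcv 1.9.3) was added after the data were seen. Lengths were those of the longest GENCODE transcript of each gene, found for 97.4% of tested genes. The tests were tried on simulated data with 200 changed genes drawn at the libraries' own depths. The changed genes were taken from those with a mean of at least 10 CPM, so recovery at lower levels was not tried. No library was made to stand apart. In a simulation of FAP against control over 13133 genes, edgeR recovered 18% of genes changed 1.25-fold, 68% at 1.5-fold, 98% at 2-fold and 100% at 4-fold, with 7 false calls among 149. Figures were drawn with matplotlib 3.10.9.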

Results

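Gene expression was measured in TC28a2 cells, an immortalised human chondrocyte line, that had been transfected with a control vector or with a vector for overexpression of FAP. FAP (fibroblast activation protein) is a membrane serine protease best known from activated fibroblasts. Each group held 3 libraries, made by DRUG-seq, a multiplexed low-cost form of RNA sequencing, from RNA taken 48 hours after transfection. The control libraries held 5736056, 9434553 and 12446373 gene counts (replicates 1, 2 and 3), and the FAP libraries 6275038, 13839743 and 13088109. Mean totals did not differ by more than the spread between libraries (two-sided exact permutation test, p = 0.5, the smallest possible p being 0.1). Between 16365 and 18358 genes had at least 1 count in a library. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Levels are TMM-scaled CPM (gene counts relative to library size), given as mean ± SD with n = 3 per group, and adjusted p-values are from edgeR's quasi-likelihood test unless another test is named. Limits given for counts cover counting error only.

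The single comparison of the design, FAP vector minus control vector, asks how raised FAP expression alters the transcriptome of these chondrocytes. The title of the series places it in work on senescent cells in osteoarthritis, with the transcription factor ZEB1 as their regulator. FAP itself (Entrez 2191; GRCh38 chromosome 2, 162170684 to 162243445) was at 266 ± 73.4 CPM in the FAP libraries and at 0.532 ± 0.612 CPM in the controls. The log2 fold change was 8.80 (SE 0.30, adjusted p = 4.229e-14). The FAP libraries held 1396, 3182 and 4733 FAP counts. The control libraries held 0, 11 and 5, and the 0 in control replicate 1 allows a level of up to 0.548 CPM. Gene counts do not separate transcripts of the vector from those of the cells' own gene. All 6 libraries matched their labels at this gene.

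Beyond FAP, few genes were called, and most of these changed by less than 2-fold. Of 13373 genes tested, 13 were higher in FAP libraries, FAP included, and 17 were lower, and 6 of these 30 changed by at least 2-fold. Genes with an unadjusted p under 0.05 numbered 1325. The number called varied with the method: DESeq2 called 98, the fit with no low-count filter 152 and limma-voom 21. The simulation missed most of the smallest changes tried, so a short list of calls does not show that few genes changed. In all 30 called genes the FAP libraries lay on 1 side of all 3 controls. Passing the test favours such genes, so this is no separate support for the calls. Of all tested genes 15.96% were separated in this way, against 10% by chance. With library totals in place of TMM the split was 13 higher and 6 lower. The calls depended on single libraries: 4 genes passed without control replicate 1, 7 without control replicate 2, 3 without control replicate 3 and 6 without FAP replicate 2, against 38 without FAP replicate 1, 22 of the 30 among them, and 248 without FAP replicate 3, all 30 among them. FAP, APCDD1L-DT and CCNE2 passed in each of these fits, with largest adjusted p-values of 1.399e-08, 0.0052527 and 0.011587.

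The lower genes included a cyclin, a collagenase and a secreted hormone. APCDD1L-DT, a long noncoding RNA gene (chromosome 20, 58515379 to 58619892), fell from 94.5 ± 5.20 to 42.7 ± 6.72 CPM (log2 fold change -1.14, SE 0.12, adjusted p = 2.823e-05). CCNE2, which encodes cyclin E2 of the passage from G1 into S phase (chromosome 8, 94880224 to 94896693), fell from 86.0 ± 8.31 to 42.0 ± 6.78 CPM (-1.03, SE 0.12, adjusted p = 2.451e-04). MMP1, interstitial collagenase (chromosome 11, 102789919 to 102798160), fell from 17.6 ± 5.80 to 7.98 ± 0.927 CPM (-1.10, SE 0.21, adjusted p = 0.0341). NUBP1, a factor of cytosolic iron-sulfur cluster assembly (chromosome 16, 10743842 to 10769351), fell from 45.5 ± 7.81 to 21.8 ± 4.47 CPM (-1.07, SE 0.16, adjusted p = 0.00341). STC2, the secreted glycoprotein stanniocalcin 2 (chromosome 5, 173314723 to 173328414), was the most abundant gene of this set and fell from 364 ± 58.8 to 220 ± 27.2 CPM (-0.72, SE 0.12, adjusted p = 0.00933). PLXNA2, a semaphorin receptor, COL17A1, a transmembrane collagen, and NFKBIE, an inhibitor of NF-kB, had log2 fold changes of -0.79, -0.77 and -0.70. SNHG9, a small nucleolar RNA host gene, and SERF1B followed at -0.63 each. The adjusted p-values of these 5 lay between 0.0056 and 0.03932.

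The higher genes included genes of matrix, adhesion and RNA binding. PTMS, parathymosin (chromosome 12, 6766363 to 6770952), rose from 104 ± 9.30 to 179 ± 28.9 CPM (log2 fold change 0.78, SE 0.12, adjusted p = 0.003819). BCL3, a nuclear partner of NF-kB proteins (chromosome 19, 44747705 to 44760044), rose from 13.0 ± 0.894 to 22.5 ± 3.14 CPM (0.78, SE 0.16, adjusted p = 0.03932). COL6A2, a chain of collagen VI of the pericellular matrix (chromosome 21, 46098112 to 46132848), rose from 138 ± 18.5 to 229 ± 41.7 CPM (0.72, SE 0.13, adjusted p = 0.0167). CDH11, a cadherin of mesenchymal cells (chromosome 16, 64943753 to 65123744), rose from 41.1 ± 2.62 to 60.8 ± 6.27 CPM (0.56, SE 0.11, adjusted p = 0.03932). ISOC2, the mRNA export factor ALYREF, PUS10, a pseudouridine synthase, and the RNA-binding protein PCBP2 had log2 fold changes of 0.69, 0.55, 0.52 and 0.51. The annotated microRNA gene MIR1244-4 was at 0.76.

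**Figure D1:**
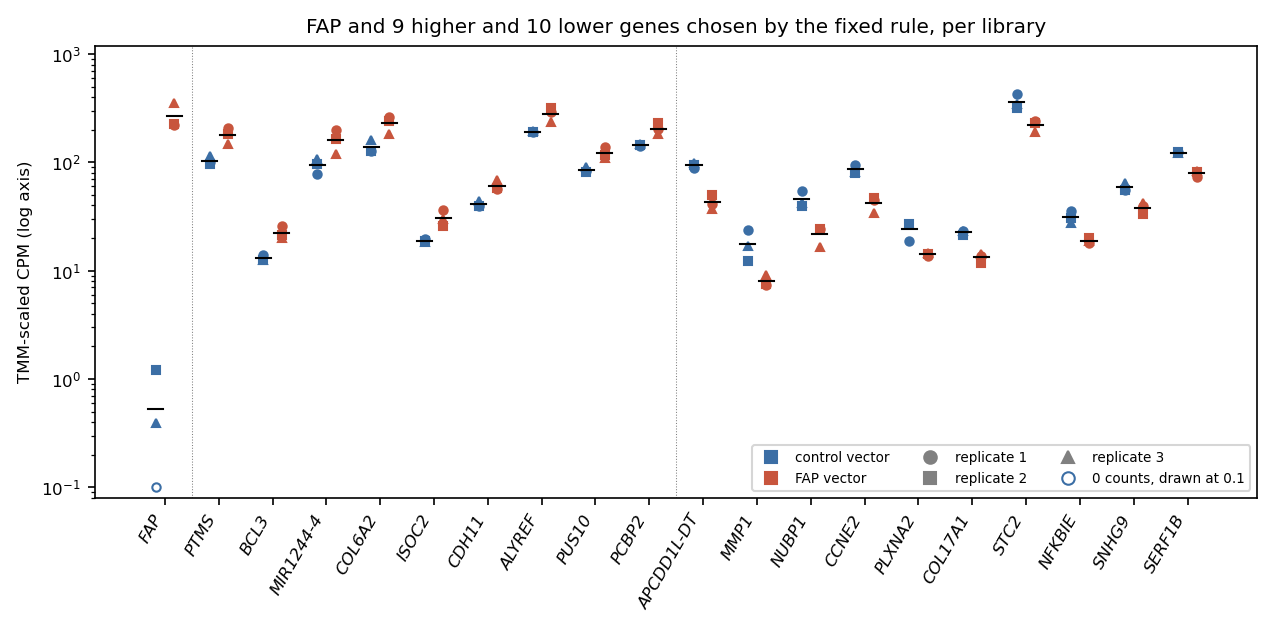
Level of FAP and of 9 higher and 10 lower genes named by the fixed rule, in TMM-scaled CPM on a log axis, for each control vector library (blue) and FAP vector library (red); marker shapes give the replicate and black lines the group means. The FAP libraries lie on 1 side of all 3 control libraries for each gene, which the rule required of the genes other than FAP. FAP replicate 3 has the highest FAP level, 351 CPM.

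The other 9 called genes fell outside the naming rule and were chosen after their values were seen. USF1, a helix-loop-helix transcription factor, had the largest change after FAP, from 2.91 ± 0.317 to 10.9 ± 5.05 CPM (log2 fold change 1.85, adjusted p = 0.0167), at a mean level below the rule's minimum. MARCKS, a substrate of protein kinase C, rose by 0.48. PLAUR, the urokinase receptor, fell from 116 ± 5.46 to 80.3 ± 1.33 CPM (-0.53, adjusted p = 0.0264). EMG1, FCF1 and TEX10, factors of ribosome assembly, had log2 fold changes of -0.53, -0.52 and -0.49. SENP5, a SUMO protease, ZNF114, a zinc finger gene, and SERF1A had -0.54, -0.60 and -0.62. Several of these genes are uncertain at the level of counting. SERF1A and SERF1B are near-identical copies with nearly equal counts in every library (670 and 676 in control replicate 1), so they are 1 observation. MIR1244-4 lies in the processed PTMA copy PTMAP9, and its 127 CPM cannot be assigned to a microRNA. No strand setting is given in the sources used here, and APCDD1L-DT overlaps APCDD1L (40.4 CPM, log2 fold change 0.01), CCNE2 overlaps INTS8 and NDUFAF6 (20.6 and 20.9 CPM), and ALYREF overlaps ANAPC11 (183 CPM). PUS10, EMG1, SNHG9, PCBP2, NUBP1 and TEX10 also overlap other measured genes.

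Genes tied to the study's question showed no called change besides MMP1. ZEB1 was at 28.8 ± 1.77 CPM in controls and 27.4 ± 4.60 CPM in FAP libraries (log2 fold change -0.06, SE 0.14, adjusted p = 0.922). ZEB2 had a log2 fold change of 0.09 (adjusted p = 0.915). The cell cycle inhibitor genes CDKN1A and CDKN2A had -0.29 (adjusted p = 0.332) and -0.01 (adjusted p = 0.978). COL1A1 and FN1 had 0.16 and 0.15 (adjusted p = 0.746 and 0.702). MMP3, MMP13 and IL6 lay at low levels, between 1.13 and 4.08 CPM, with log2 fold changes of -0.84, -0.58 and -0.13. DPP4, the protease closest to FAP, was under 1 CPM in both groups. ACAN, COL2A1, ADAMTS5 and CXCL8 had at most 15 counts in any library and were removed by the low-count filter. Without that filter their log2 fold changes were -1.07, -1.63, -0.64 and 0.50 with SEs of 0.71, 1.46, 1.27 and 1.28, and none passed (smallest adjusted p = 0.742).

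Among 26 fixed gene lists with at least 5 tested members, 11 moved against the other genes (limma's camera, preset correlation 0.01), 4 upward and 7 downward. None passed with an estimated correlation between members, and none with fry, a test of whether a list moves on balance 1 way, while 16 passed fry's test of change in either direction. With the estimated correlation the adjusted p-values of the 11 lists lay between 0.2924 and 0.86189. The estimate itself was below the preset in the protease, secretory phenotype, immediate early and histone lists (-0.0321, 0.00536, 0.00553 and -0.0622). Their unadjusted camera p still rose, from 0.0113, 0.00604, 0.0108 and 0.00894 to 0.0467, 0.0458, 0.0562 and 0.0511. Closer correlation of members than the preset therefore did not cost those 4 calls. The settings of camera differ in more than the correlation value. In the other called lists the estimate was above the preset, up to 0.784 for ribosomal proteins. After a per-library correction for transcript length and GC content, chosen after the data were seen, the cartilage, G2 and M phase, interferon and cholesterol lists passed and the 7 other called lists did not. FAP replicate 3 stood apart from FAP replicates 1 and 2 by chi-square per degree of freedom (17.2 and 16.9, against 5.99 between those). By rank it did so less clearly. Its Spearman correlations with FAP replicates 1 and 2 were 0.98225 and 0.98948, against 0.98898 between those. In the fit without FAP replicate 3, 6 lists passed under the preset correlation and none with an estimated correlation (smallest adjusted p = 0.495).

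The cartilage and matrix lists were shifted upward against other genes only under the preset correlation. Of the 30 cartilage matrix and chondrogenic genes only 5 were tested, all with positive log2 fold changes (median 0.50, adjusted p = 7.153e-04; adjusted p = 0.292 with an estimated correlation). The shift covers these 5 only. ACAN and COL2A1 belong to the list but had too few counts to be tested. Without the low-count filter their log2 fold changes were -1.07 and -1.63, with SEs of 0.71 and 1.46. Of the 5 tested none passed over all genes, and 4 were higher adjusted over the list alone. These were BGN (biglycan, log2 fold change 0.53), VCAN (versican, 0.40), SOX9, the main transcription factor of chondrocytes (0.36, adjusted p = 0.416 over all genes), and MATN2 (0.81, from 2.16 to 3.95 CPM). Of 34 fibrillar, basement membrane and fibroblast matrix genes, 24 had positive values (median 0.15, adjusted p = 0.0231; adjusted p = 0.540 with an estimated correlation). COL6A2 passed over all genes and adjusted over the list alone. This call was lost without control replicate 1 (median 0.05, adjusted p = 0.402) and without FAP replicate 2 (median 0.10, adjusted p = 0.143), and the median was 0.09 without FAP replicate 3. Of 5 hypertrophic chondrocyte genes tested, none passed over all genes or adjusted over the list alone (adjusted p = 0.857), RUNX2 being at 0.18. Of 21 mesenchymal transition genes, CDH11 alone passed over all genes and adjusted over the list alone, and the list did not (adjusted p = 0.362). TGF-beta targets did not pass as a list (adjusted p = 0.513). Adjusted over the list alone, 2 were higher, TGFB1 (0.52) and CDKN2B (0.78), and 2 were lower, CCN2 (-0.39) being 1 of them.

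The lists of matrix proteases and of the senescence-associated secretory phenotype were shifted downward against other genes, again only under the preset correlation. Of 27 proteases, 20 had negative values (median -0.13, adjusted p = 0.0294; adjusted p = 0.292 with an estimated correlation), and MMP1 was the 1 member lower over all genes and adjusted over the list alone. Of 22 secretory phenotype genes, 15 were negative (median -0.15, adjusted p = 0.0231; adjusted p = 0.292 with an estimated correlation). None passed over all genes, and 4 were lower adjusted over the list alone. These were the stanniocalcin STC1 (-0.61), IGFBP5 (-0.53), INHBA (-0.35) and ANGPTL4 (-0.67). Both calls were lost without control replicate 3, FAP replicate 2 or FAP replicate 3 (largest adjusted p = 0.221 and 0.201). The protease median was -0.21 without FAP replicate 2 and -0.08 without FAP replicate 3, and the secretory phenotype median was -0.10 without control replicate 3 and -0.06 without FAP replicate 3. Among 11 protease inhibitors 2 were lower adjusted over the list alone, TIMP2 (-0.30) being 1 of them, and the list did not pass (adjusted p = 0.770). The lists of senescence-linked inhibitors with nuclear lamina genes (17 tested, adjusted p = 0.853) and of p53 targets (26 tested, adjusted p = 0.261) had no member past over all genes or adjusted over the list alone. With a filter of at least 10 CPM in 3 libraries, under the preset correlation, the p53 list passed downward (median -0.08, adjusted p = 0.0415) and the protease list did not pass (adjusted p = 0.0546). In the main fit the p53 list had an adjusted p of 0.478 with an estimated correlation.

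Among cell cycle genes CCNE2 was the called member, and the G2 and M phase list was shifted upward under the preset correlation only. Of 42 such genes, 33 had positive values (median 0.12, adjusted p = 0.00102; adjusted p = 0.319 with an estimated correlation). The spindle checkpoint kinase TTK (0.47) was higher adjusted over the list alone, no member passed over all genes, and KIF23, a kinesin of cytokinesis, was at 0.31. Of 39 S phase genes CCNE2 alone passed over all genes and adjusted over the list alone, and the list did not (adjusted p = 0.232). The histone list was shifted downward under the preset correlation (12 tested, 9 negative, median -0.08, mean -0.23, adjusted p = 0.0291; adjusted p = 0.292 with an estimated correlation), H2BC4 (-1.23) being the 1 lower adjusted over the list alone and none passing over all genes. The cartilage and the G2 and M phase lists passed without each library in turn (largest adjusted p = 0.0408 and 0.0485), the G2 and M phase median being 0.08 without FAP replicate 3. The histone call was lost without control replicate 1, control replicate 3 or FAP replicate 2 (largest adjusted p = 0.0888). The histone median was -0.20 without control replicate 2, -0.05 without FAP replicate 2 and -0.17 without FAP replicate 3. With the 10 CPM filter the histone list did not pass (adjusted p = 0.198), and the cartilage list had too few members to test.

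The interferon response and immediate early lists were shifted downward under the preset correlation, with no member called over all genes. Of 39 interferon response genes, 28 had negative values (median -0.13, adjusted p = 0.00342; adjusted p = 0.478 with an estimated correlation). None passed over all genes, and 5 were lower adjusted over the list alone, the antiviral genes IFIT3 (-0.37), RSAD2 (-0.51), ISG20 (-0.64), IFI27 (-0.47) and HERC6 (-0.51). The call was lost without control replicate 2 (median -0.04, adjusted p = 0.317). Of 24 immediate early genes, 17 were negative (median -0.13, adjusted p = 0.0294; adjusted p = 0.292 with an estimated correlation). KLF2 (-0.81) was lower adjusted over the list alone, none passed over all genes, and the call was lost without control replicate 3, FAP replicate 2 or FAP replicate 3 (largest adjusted p = 0.282), the median being -0.06 without control replicate 3. The NF-kB list did not pass (21 tested, adjusted p = 0.186, or 0.478 with an estimated correlation). Under the preset correlation it passed downward with the 10 CPM filter (adjusted p = 0.0268) and without FAP replicate 1 (adjusted p = 0.0315). It held BCL3, higher, and NFKBIE, lower, over all genes, and adjusted over the list alone also TNFRSF9 (0.94), higher, and TNFAIP3 (-0.91), a feedback inhibitor, lower.

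Under the preset correlation the cholesterol synthesis list was shifted upward and the oxidative phosphorylation and ribosomal protein lists downward, by small amounts and with no member called. Of 25 cholesterol genes, 18 had positive values (median 0.12, adjusted p = 0.0231; adjusted p = 0.540 with an estimated correlation), with SQLE at 0.31 and MSMO1 at 0.34. Of 50 nuclear genes of oxidative phosphorylation, 38 were negative (median -0.10, adjusted p = 0.00343; adjusted p = 0.582 with an estimated correlation), with NDUFA1 at -0.35. Of 50 ribosomal protein genes, 38 were negative (median -0.06, adjusted p = 0.0406; adjusted p = 0.862 with an estimated correlation), with RPL24 at -0.30. No member of these lists passed over all genes or adjusted over the list alone. Each call was lost without FAP replicate 2 and without 2 or 3 of the other libraries, with largest adjusted p-values of 0.211, 0.118 and 0.606. The lost fits were those without control replicates 1 and 3 and FAP replicate 1 for cholesterol, control replicate 2 and FAP replicate 3 for oxidative phosphorylation, and control replicates 1 and 2 and FAP replicate 3 for the ribosome. The direction of the ribosomal protein list turned without FAP replicate 3 (median 0.02, adjusted p = 0.606), and its median was -0.02 and -0.10 without control replicates 2 and 3 and -0.14 without FAP replicate 1. The cholesterol median was 0.21 without FAP replicate 3, and that of oxidative phosphorylation -0.06 without control replicate 2, -0.15 without FAP replicate 1 and -0.05 without FAP replicate 3. With library totals in place of TMM the ribosomal protein list had a median of -0.0029 (adjusted p = 0.157), and with the 10 CPM filter it did not pass either (adjusted p = 0.0838). Library totals also moved the medians of the oxidative phosphorylation, histone, protease, interferon and immediate early lists, to -0.04, -0.02, -0.07, -0.08 and -0.08, with each call kept.

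Lists of stress and metabolism did not pass: the unfolded protein response (adjusted p = 0.261), ATF4 targets (adjusted p = 0.883), heat shock (adjusted p = 0.273), hypoxia and glycolysis (adjusted p = 0.462) and autophagy, lysosome and FOXO targets (adjusted p = 0.770). HERPUD1, SLC7A5, SLC2A1 and SQSTM1, with the smallest p of their lists, had log2 fold changes of 0.49, 0.43, -0.30 and -0.32. Of these lists, heat shock had members past adjusted over the list alone, HSPA1B (0.38) higher and HSPB8 (-0.42) lower. Markers of other cell types did not pass camera, endothelial at adjusted p = 0.883 and haematopoietic at 0.327. In fry's test of change in either direction, which makes no comparison with other genes, the 5 endothelial genes had an adjusted p of 2.515e-04, the smallest of the 26 lists. PECAM1, an endothelial gene, was higher adjusted over its list alone, at 0.444 CPM in controls and 1.70 CPM in FAP libraries. The epithelial list (3 tested) and the osteoblast, adipocyte and muscle list (2 tested) were too small to test, and mitochondrially encoded transcripts were not analysed here. Median, mean and test differed in sign for protease inhibitors, the lamina list, p53 targets, ATF4 targets, the autophagy list and the endothelial list, none of which passed.

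**Figure D2:**
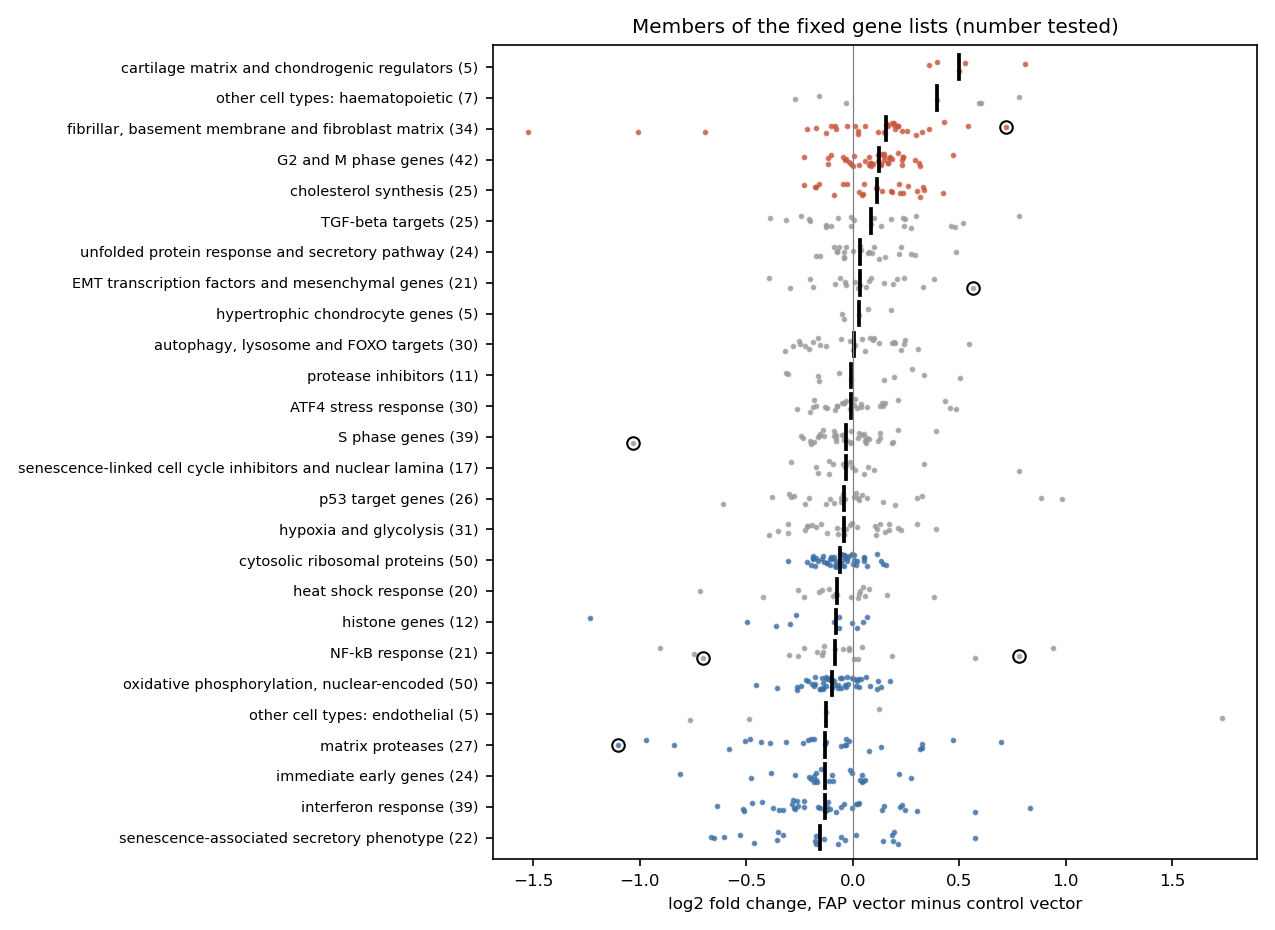
Log2 fold change, FAP vector minus control vector, of each tested member of the 26 gene lists (1 point per gene, vertical bars for list medians), sorted by median. Red and blue mark the 4 lists higher and the 7 lower by camera with its preset correlation, none of which passed with an estimated correlation; circles mark members past the threshold over all genes.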

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

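The length and GC correction was chosen after the data were seen. FAP stayed past the threshold under all 21 alternatives, with log2 fold changes from 8.46 to 9.86, and the 30 called genes kept their sign under each alternative that tested them; 3 (FAP, APCDD1L-DT, CCNE2) stayed past in all. For the others the cause of a lost call was not tested, except that a stricter threshold calls fewer genes by construction. Genes higher and lower numbered 26 and 72 by DESeq2, 54 and 98 with no low-count filter, and 2 and 6 at an adjusted p under 0.01. Limma-voom gave 7 higher, the 1.5-fold minimum 8 higher, library totals 6 lower, an adjusted p under 0.1 28 lower, and counts thinned to the smallest library 11 lower. DESeq2 shared 29 of the 30 calls. Leaving out each library gave 1 to 109 higher genes, 2 to 139 lower genes and 3 to 11 lists, the fewest genes in all without control replicate 3 and the most without FAP replicate 3. The replicate block gave 16 higher and 28 lower genes, all 30 calls included, and 11 lists. Libraries of the same number did not deviate together (correlations across genes -0.0039, 0.0203 and -0.0041), and not every library correlated best with its own number, so the numbers are not treated as pairs. List calls went from 11 to 0 with an estimated correlation, 0 with directional fry and 4 with the length and GC correction; the 10 CPM filter gave 9, of which 7 were among the 11.

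Signs turned for 8 uncalled genes, of which DPP4 lay under 1 CPM with a log2 fold change of 0.473 (SE 0.829). Library totals gave RUNX3 0.00412, DES 0.0131 and CDKN2A 0.0407; limma-voom gave DES 0.0241 and DPP4 -0.565. Thinned counts gave ZEB1 0.0311 and CDKN2A 0.0101, and the length and GC correction gave CDKN2A 0.0376. Leaving out each library gave DES -0.583 (FAP replicate 2) to 0.340 (control replicate 1; 0.333 without FAP replicate 3), ZEB1 -0.213 to 0.0214 (FAP replicates 3 and 2) and ZEB2 -0.0672 to 0.202 (FAP replicates 3 and 1; -0.0491 without control replicate 2). It gave CDKN2A -0.0272 to 0.0135 (FAP replicates 1 and 3), COL1A1 -0.0213 to 0.270 (control replicates 1 and 3) and IL6 -0.248 to 0.165 (control replicates 1 and 3). Depth limits genes of a few CPM, which the simulation did not change. By the simulated recovery most changes of the smallest size tried would be missed even at 10 CPM or more.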

Other observations

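The tests of the length, GC and depth explanations for separate groups of lists were chosen after the outcome of each list was seen, and so cannot decide for or against an explanation. Ribosome assembly genes stood out among the lower genes (EMG1, FCF1, TEX10), which led to the hypothesis that ribosome biogenesis genes as a group were lower in FAP libraries. In a textbook list without the genes that drew attention, 63 of 82 tested genes had negative values (median log2 fold change -0.10), and camera gave an adjusted p of 2.514e-04 (adjusted p = 0.540 with an estimated correlation). No member was called over all genes, but the called genes EMG1, FCF1 and TEX10 had been left out of the list. The list passed after the length and GC correction (adjusted p = 2.363e-04) and without FAP replicate 3 (adjusted p = 1.091e-07). The list was not tested with any other library left out. It was found and tested on the same libraries, so a lower level of these transcripts may be a real effect of FAP or a feature of these 6 libraries. A parallel hypothesis, that small nucleolar RNA host genes as a group were lower, was not borne out (21 tested, adjusted p = 0.594), although SNHG9 was called.

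Several gene lists moved together by small amounts under camera's preset correlation, and none of the 11 passed with an estimated correlation. Among technical explanations, transcript length or GC bias between libraries left 4 of the 11 calls after correction, between the bounds set beforehand. The 4 lists that stayed past (cartilage, G2 and M phase, interferon and cholesterol) had medians of 0.44, 0.11, -0.13 and 0.14 after it. They were grouped by that outcome, so their staying past is no test of bias as a cause. Before the correction they had adjusted p-values of 0.292 to 0.540 with an estimated correlation. Bias cannot be told apart for oxidative phosphorylation, ribosomal proteins and histones, whose calls ended. In the longest transcripts, which the correction used, these lists had median lengths of 1296, 1917 and 771.5 bases, the shortest of the 11. Their log2 fold change medians shrank to at most 52.8% of their size (from -0.10, -0.06 and -0.08 to -0.05, -0.03 and -0.04). Nor can bias be told apart for the matrix, protease, secretory phenotype and immediate early lists. Their adjusted p rose to between 0.0515 and 0.0881 while medians kept 72.1% to 121% of their size. The library depth difference between groups predicted at least 50% of the shift in 2 of 11 lists. The upper bound of the prediction, at 2 standard errors, reached it in 3, the matrix, oxidative phosphorylation and ribosomal protein lists. The prediction used a slope on depth within groups, fitted to only 6 libraries, for which a bound of 2 standard errors is narrow. The lists were also divided by this outcome, so the bound cannot argue against depth for the other 8. Depth stays open for all 11 lists. Of the 10 splits of the 6 libraries the real 1 gave 11 lists and the highest other 5, too few splits for a share under 0.05.

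The real grouping called 30 genes and the highest of the other splits 0, but 10 splits are too few for a share under 0.05, the real 1 being 1 of 10.

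FAP replicate 3 stood apart: without it 248 genes passed, all 30 calls included, and the biological coefficient of variation fell from 11.8% to 9.75%. The 248 genes include near-identical SNAR-A copies and so are fewer separate observations. Its deviations followed transcript length (Spearman's rho 0.288 across genes, which are not independent replicates) and, inversely, GC content (-0.216). Such trends were not particular to it, as control replicate 2 had -0.224 with length and 0.293 with GC content. With all 6 libraries and the length and GC correction 28 genes passed, 25 of them among the 30. Whether the correction removed the trends was not checked, and it used the longest transcript of each gene. The count therefore argues against a length or GC trend of FAP replicate 3 as the reason only as far as the correction removed it. A weaker response in FAP replicate 3 would give it a negative slope against the others, and its mean slope was -0.220. FAP replicates 1 and 2 had 0.03 (the mean of -0.133 and 0.202) and 0.19. The 3 mean slopes offset each other by construction and could not all be positive, so this does not establish a weaker response. A technical shift shared by FAP replicates 1 and 2 would give the same slope and stays open, and FAP itself was highest in FAP replicate 3.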
